A study of Petromyzon marinus with 6 samples.

How the data were processed

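RNA was measured in whole embryos of the sea lamprey (Petromyzon marinus), a jawless vertebrate, in 6 paired-end RNA-seq libraries. Each library came from 1 developmental stage, per the labels: days 1, 2 and 2.5 after fertilization, and days 3, 4 and 5. Embryos were frozen and their RNA was extracted with Trizol before NEBnext library preparation, per the labels' protocols. There was 1 library per stage, and no source used here says how many embryos or which spawnings went into each. No difference between 2 stages therefore has a replicate check, and intervals cover counting error only.

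The deposited values were made with RSEM, a program that shares fragments among transcripts that they match equally well, per the submitters' processing notes; its version, the aligner and the assembly method are not given in the sources used here. Per the file headers, each file gives for every transcript its length and effective length in nucleotides, an expected count, a TPM and an FPKM. The expected counts are the authors' estimated counts of fragments and are not normalized. Between 39.2% and 50.6% of the nonzero expected counts in a library differed from a whole number by more than 0.005, because shared fragments had been divided. The deposited TPM values are divided by effective length and scaled to the same sum in every library, and were used only as an alternative scaling. The deposited FPKM values were not used.

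The transcripts are 145913 assembled contigs of 500 to 17827 nt. Their identifiers have the form that a de novo transcript assembler writes: a component, then a numbered sequence within it. RSEM was run with every contig as its own gene, as the identical gene and transcript columns show. In total 77561 contigs lay in 18910 components of 2 or more contigs, so that near-identical contigs (splice forms, alleles or close copies) divided their reads among themselves. Counts were therefore also summed by component, giving 87262 components. This alternative, and every test on components, was chosen after seeing the data, and component values stand beside the planned contig values. A component may hold more than 1 gene, and a gene may be split over components.

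The files do not pair contigs with gene names, and none of the 145913 identifiers occurs among the 45433 genes of the reference name table (assembly UKy_Petmar_22M1.pri1.0). The 15 gene lists that had been fixed before the data were examined could therefore not be used, nor could the rule that names genes by size of change. In its place, at most 2 contigs higher and 2 lower at day 5 are named, as the rule provides for that case: those with the largest log2 fold between day 1 and day 5 among contigs with 100 or more counts in the higher library. No genome coordinates are given, since no genome position of a contig was used here.

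Expected counts were rounded to whole numbers. Contigs with a total of 60 or more counts over the 6 libraries (a mean of 10) were tested: 47525 contigs and, by the same rule, 31146 components. The filtered contigs held 98.6% to 99.4% of each library's counts. CPM values were computed from library totals scaled by the TMM factors of edgeR 4.0.16, which ranged from 0.815 at day 4 to 1.19 at days 1 and 2.5. Folds are on the log2(CPM + 0.5) scale, which understates the change of low contigs. A contig was called 4-fold higher or lower between 2 libraries when its fold passed 4 and the exact 95% Clopper-Pearson counting interval of the fold excluded 1. In simulated libraries of day 1 and day 5 depth with counting noise only, this rule on 47525 contigs recovered 74 of 100 contigs changed 8-fold and 53 of 100 changed 5-fold, with 0 calls among unchanged contigs.

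A contig was called peaked at a stage when its highest CPM was at least 4 times the median of the other 5 libraries. Contigs with 100 or more counts at day 1 and fewer than 3 at day 4 and at day 5 were counted as no longer detected. The mirror set had 100 or more counts at day 5 and fewer than 3 at day 1 and day 2. The main test, a linear trend of log expression over the 6 days, used edgeR's quasi-likelihood test with 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Its spread is the deviation from a straight line, so that real non-linear change counts as error. In simulated counts with the fitted dispersions, this test recovered 9 of 100 contigs with a slope of 1 log2 unit per day and 59 of 100 with a slope of 2, with 0 calls among the unchanged of 47525 contigs. For 31146 components it recovered 43 and 87 of 100, with 2 calls among the unchanged.

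Alternatives were DESeq2 1.42.0 size factors, the deposited TPM, no filter, a pseudocount of 5, an 8-fold threshold, DESeq2's Wald test, limma 3.58.1 on log2(TPM + 1), the rank of the stage in place of the day, and leaving out each library in turn. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.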

Results

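The 6 libraries, 1 per stage, held between 15503476 (day 5) and 21910119 (day 1) expected counts. Days 2, 2.5, 3 and 4 had 17598545, 18387664, 20769683 and 19845393. The series was made to follow gene expression over early sea lamprey development. Sea lamprey embryos are known to discard part of their genome from somatic cells early in development, so transcripts that vanish are of interest beside those that appear. The 2 contigs with the most counts over the 6 libraries were 7607 and 6757 nt long. The most abundant transcript unit was a component of 2 contigs. It took 9.11% of the counts at day 1, 6.47% at day 2, 2.60% at day 2.5, 8.34% at day 3, 9.72% at day 4 and 7.79% at day 5. Its exact 95% Clopper-Pearson intervals were narrow, at 9.10% to 9.12% for day 1 and 2.59% to 2.61% for day 2.5. The 100 most abundant contigs of each library took 22.7% of the counts at day 1, 18.6% at day 2.5 and 32.3% at day 4.

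The 6 stages fell into an early group and a late group. The libraries of days 1, 2 and 2.5 resembled one another, with Spearman correlations across components of 0.86 to 0.95, and days 4 and 5 reached 0.90. Across components day 3 lay between them: its correlation was 0.80 with day 2.5, 0.85 with day 4 and 0.79 with day 5. Day 1 correlated least with day 4 (0.55) and slightly more with day 5 (0.62). Across contigs every one of these values was lower, with 0.79 between day 1 and day 2, 0.64 between day 2.5 and day 3 and 0.37 between day 1 and day 4. Among the 1000 most abundant contigs the correlation of day 1 with day 5 was negative, at -0.33, against 0.46 across all tested contigs. Those 1000 were chosen by their mean abundance in the same libraries, so their correlations place no stage with another. In them day 3 had 0.80 with day 4, 0.69 with day 5 and 0.283 with day 2.5, while across all tested contigs it had 0.74, 0.64 and 0.64. Pearson correlations across contigs ran from 0.49 (days 1 and 4) to 0.89 (days 2 and 2.5). These are correlations across transcripts, which are not independent replicates.

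**Figure D1:**
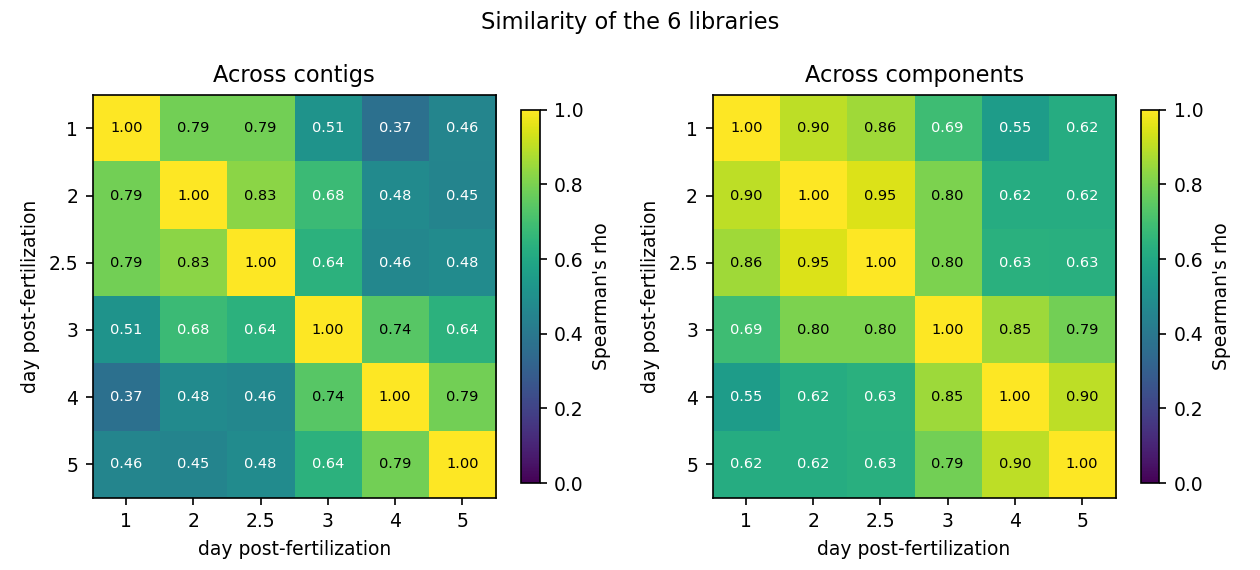
Spearman correlation of log2(CPM + 0.5) between each 2 of the 6 libraries (days post-fertilization on both axes), across 47525 contigs (left) and 31146 components (right). Days 1, 2 and 2.5 form one bright block and days 4 and 5 another, with day 3 between them.

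From day 1 to day 4, the number of transcripts with any count was higher at each later stage once depth was made equal. At the depth of the day 5 library, 37673 components were expected to have 1 or more counts at day 1 and 52968 at day 2. The values were 56929 at day 2.5, 60419 at day 3 and 61638 at day 4. They were computed by drawing counts with replacement, which loses more rare transcripts than thinning does. Day 5, the smallest library, kept its observed 64169 components, so its rank against days 3 and 4 is not settled. The largest difference of consecutive stages lay between day 1 and day 2. For contigs the values ran from 55222 at day 1 to 84684 at day 4, and 87071 were observed at day 5. Without equalising depth, 41859 components had a count at day 1, 67508 at day 4 and 64169 at day 5. Most of these additional transcripts were rare: the 54696 components with fewer than 3 counts at day 1 took 1.01% of the counts at day 2, 2.21% at day 3 and 3.11% at day 5. Each value rests on 1 library.

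**Figure D2:**
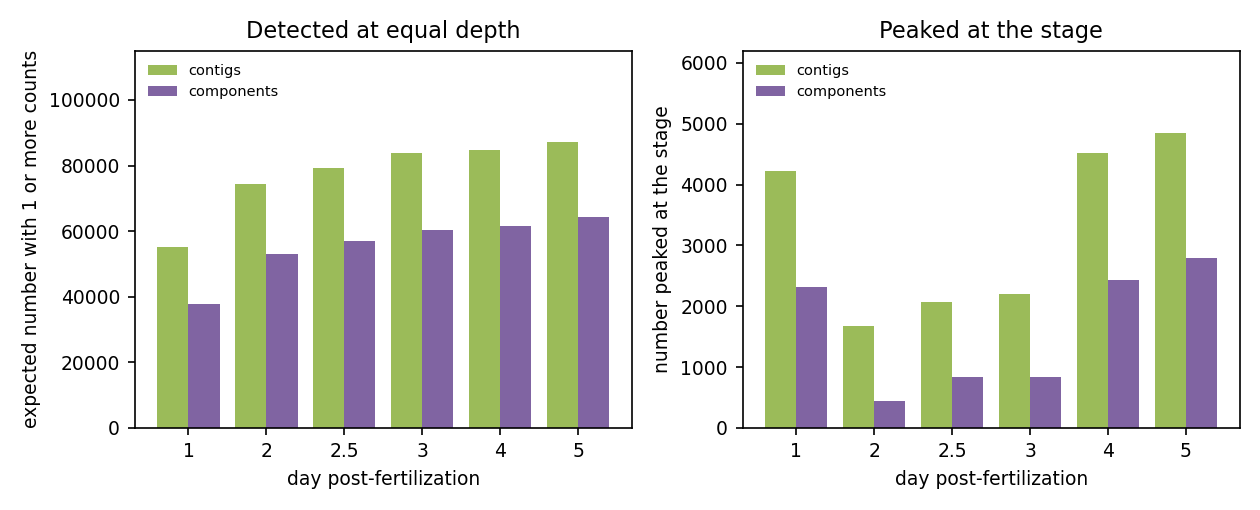
Left: expected number of contigs and components with 1 or more counts at each day, by drawing counts with replacement to the depth of day 5. Day 5 itself shows its observed number. Right: number of contigs and components peaked at each day, meaning a highest CPM at least 4 times the median of the other 5 libraries. On the left, components rise from 37673 at day 1 to 61638 at day 4, and on the right peaks are fewest at day 2.

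Between day 1 and day 5, 9014 contigs were 4-fold or more higher and 7157 were 4-fold or more lower, together 34.0% of the 47525 tested. Summed by component, 5154 were higher and 3872 lower, or 29.0% of 31146. The components lower at day 5 had taken 26.1% of all counts at day 1 and took 2.11% at day 5. Those higher at day 5 had taken 4.24% at day 1 and took 41.4% at day 5. Of the higher components, 2330 had fewer than 3 counts at day 1, and of the lower ones 670 had fewer than 3 at day 5. The median component in the higher group went from 0.159 CPM at day 1 to 3.73 at day 3 and 7.38 at day 5. The median in the lower group went from 14.9 CPM at day 1 to 9.42 at day 2.5, 3.95 at day 3, 1.42 at day 4 and 1.33 at day 5. Which direction prevailed depended on the scaling: 57.1% of the changed components were higher with TMM and 43.3% with the deposited TPM, where the median component shifted by -0.27 on the log2 scale, against 0.22 with TMM. For contigs the corresponding shares were 55.7% and 42.4%.

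With TMM, most of these components had their largest step between day 2.5 and day 4. Of the components 4-fold higher at day 5, 44.3% had their largest step between days 2.5 and 3, 22.7% between days 3 and 4, 17.4% between days 1 and 2, 10.4% between days 4 and 5 and 5.14% between days 2 and 2.5. Of those lower at day 5, 41.2% had their largest step between days 3 and 4 and 38.4% between days 2.5 and 3. In 786 of the higher and 668 of the lower components no interval went the other way.

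The 2 contigs furthest above their day 1 level were lcl|comp291748_c0_seq1 (2539 nt) and lcl|comp237504_c0_seq1 (2000 nt). The first had 0 counts at day 1, 4.53 CPM at day 2.5, 418 CPM at day 3, 2364 CPM at day 4 and 6198 CPM at day 5. Against a floor of 3 counts in the day 1 library it was at least 53897-fold higher at day 5. Its whole component of 4 contigs went from 21 counts at day 1 to 94787 at day 5, a log2 fold of 12.36. The second had 0 counts at day 1, 146 CPM at day 2.5, 1602 CPM at day 3 and 2874 CPM at day 5. That was 24990-fold above the same floor, with a lower interval limit of 20323. Its component of 8 contigs already had 230 counts at day 1, and its log2 fold was 8.27.

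The 2 contigs furthest below their day 1 level were lcl|comp293716_c0_seq1 (3086 nt) and lcl|comp277144_c1_seq2 (4577 nt), and their components changed far less than they did. The first had 1528 CPM at day 1, 999 CPM at day 3, 80.8 CPM at day 4 and 0 counts at day 5, at least 6874-fold lower than at day 1 against a floor of 3 counts in the day 5 library. Its component of 6 contigs kept 4512 counts at day 5, against 50408 at day 1, a log2 fold of -2.58. The second had 563 CPM at day 1, 229 at day 2, 675 at day 2.5, 105 at day 3 and 0 counts at day 5. It was 2533-fold lower by the same floor, with an upper interval limit of 0.000485. Its component kept 1054 counts at day 5, with a log2 fold of -2.97. In edgeR's quasi-likelihood trend test the 4 contigs had Benjamini-Hochberg adjusted p-values of 0.070, 0.14, 0.19 and 0.15, in the order named. Their components had adjusted p-values of 0.019, 0.024, 0.027 and 0.025 in the same test.

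**Figure D3:**
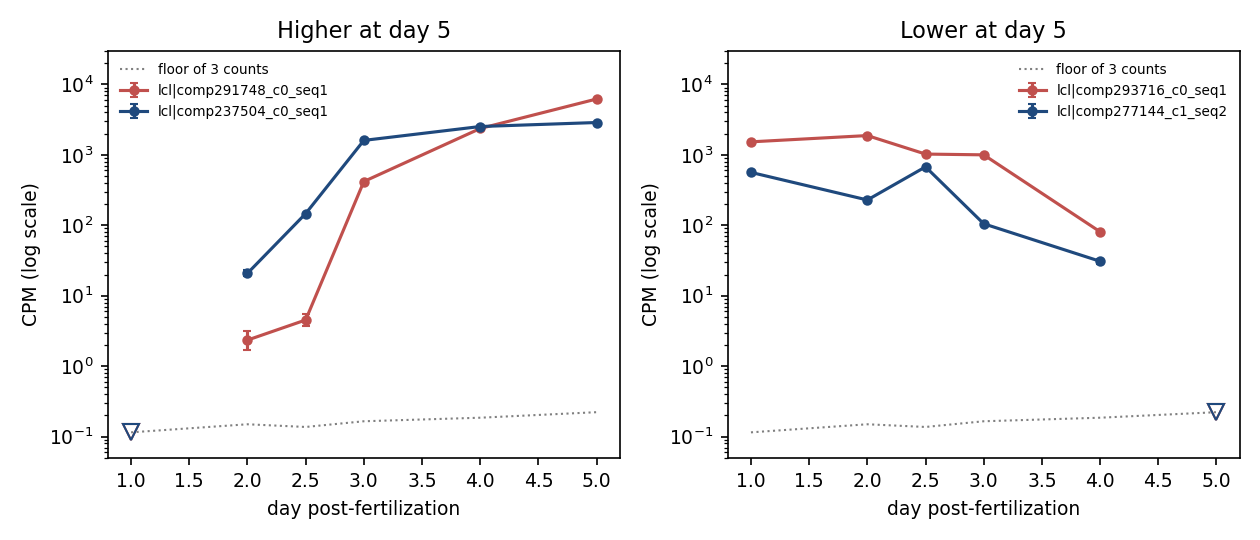
CPM of the 4 named contigs at each day on a log scale (x axis, days post-fertilization), with exact 95% Poisson counting intervals as bars and the floor of 3 counts per library as a dotted line; open triangles mark 0 counts. The left pair climbs from 0 counts at day 1 to 6198 and 2874 CPM at day 5, and the right pair falls to 0 counts at day 5.

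Among consecutive stages, the half-day step from day 2.5 to day 3 held the most change. In that interval 1611 components were 4-fold higher and 749 lower, 7.58% of those tested. Days 2 and 2.5 differed least, with 200 components higher and 92 lower, or 0.938%. Of these 200, 82 belonged to a set of 90 components whose counts lay almost wholly in the libraries of days 2.5, 4 and 5, and without that set 118 were higher and 92 lower. The same set held 83 of the 749 components lower at day 3 than at day 2.5. From day 1 to day 2, 1329 components were higher and 209 lower, an 86.4% share of higher ones that was 87.4% with the deposited TPM. From day 3 to day 4, 820 were higher and 634 lower, and from day 4 to day 5, 410 were higher and 263 lower. The components higher at day 3 than at day 2.5 went from 5.21% of the counts to 22.6%. The most abundant component was one of them, near the 4-fold limit, and without it the shares were 2.61% and 14.3%. With the deposited TPM the change from day 2.5 to day 3 was mostly downward, with 37.4% of 3975 changed components higher and a median shift of -0.48 on the log2 scale. From day 3 to day 4 the TPM median shift was -0.14, and from day 4 to day 5 the DESeq2 median shift was -0.11. From day 3 to day 4 the share of higher components was 56.4% with TMM, 66.1% with DESeq2 size factors and 44.4% with TPM, and from day 4 to day 5 it was 60.9%, 49.5% and 58.0%.

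The same intervals counted by contig gave more change, and as a ratio to the component count most so where the component sums changed least. From day 2 to day 2.5, 1662 contigs were higher and 1518 lower, against the 292 components. The other intervals had 4906 changed contigs (days 1 to 2), 7390 (days 2.5 to 3), 5066 (days 3 to 4) and 3950 (days 4 to 5). In 573 contigs, but only 18 components, the libraries of days 1, 2.5 and 5 all lay 4-fold above or below those of days 2, 3 and 4. Comparisons inside each of these library sets, added after this was seen, gave 2614 changed components from day 2 to day 3, 2528 from day 1 to day 2.5 and 6908 from day 2.5 to day 5.

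**Figure D4:**
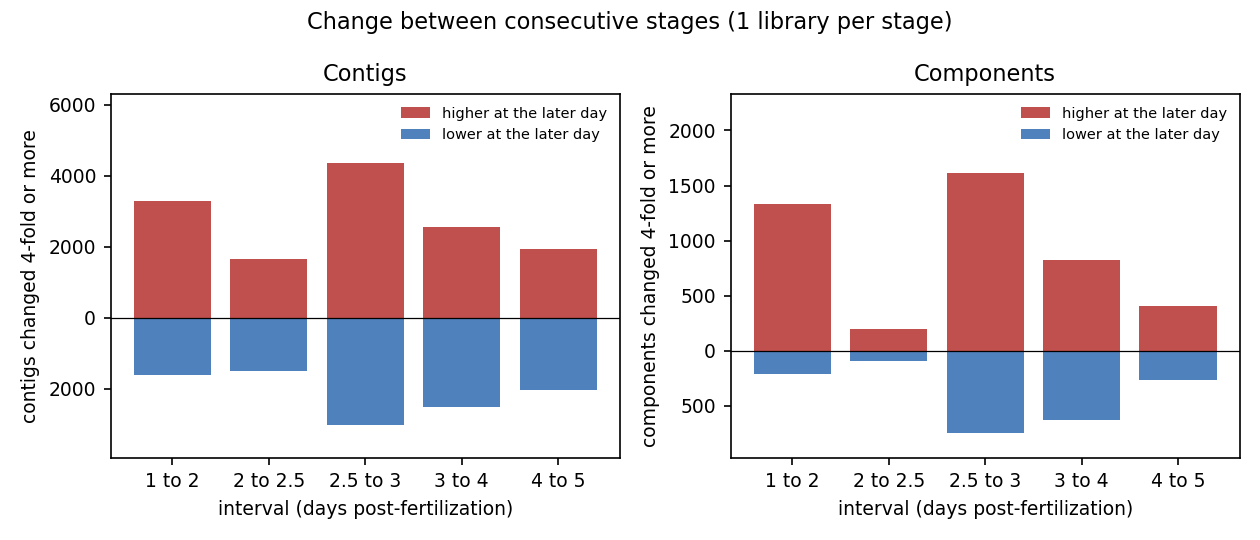
Number of contigs (left) and components (right) changed 4-fold or more between consecutive stages, with those higher at the later day above 0 and those lower below 0. The interval from day 2.5 to day 3 has the tallest bars in both panels, and days 2 to 2.5 nearly vanish once contigs are summed by component (200 higher, 92 lower).

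Fewer components peaked at days 2, 2.5 and 3 than at days 1, 4 and 5. The rule itself favours days 1 and 5, where any steady fall or rise peaks, and can disfavour stages sampled close together. Without the day 2.5 library, contigs peaked at day 2 went from 1680 to 3058. Of 9670 components peaked at a stage, 2796 peaked at day 5, 2424 at day 4 and 2321 at day 1, while 449 peaked at day 2, 838 at day 2.5 and 842 at day 3. Those peaked at day 1 had a median of 9.08 CPM there, 4.39 at day 2, 3.66 at day 2.5 and 1.21 at day 3. Those peaked at day 5 had a median of 7.23 CPM there and took 24.1% of the day 5 counts. Components peaked at day 2.5 had a median of 3.41 CPM, between 1.09 at day 2 and 0.549 at day 3. Of these 838, 69 belonged to the set of 90 components counted almost wholly at days 2.5, 4 and 5. By contig, 19552 were peaked, with 4230 at day 1, 1680 at day 2, 2075 at day 2.5, 2202 at day 3, 4515 at day 4 and 4850 at day 5. Day 1 became the largest class of contigs with the deposited TPM (6766), without the day 2 library (5595) and without the day 2.5 library (5803). Day 4 became the largest class with DESeq2 size factors (5709) and with no filter (20393).

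With edgeR's quasi-likelihood test and the day as a straight line, many components and 0 contigs had a trend over the 6 days. For components, it called 3652 rising and 3533 falling at an adjusted p of 0.05. The rising ones had a median slope of 1.27 log2 units per day (interquartile range 0.82 to 1.92) and the falling ones -1.02 (-1.34 to -0.77). Of the rising components, 3184 were also 4-fold higher at day 5 than at day 1, and 3058 of the falling ones were 4-fold lower. The count for contigs depended on the test: 0 of 47525 passed here, with 14582 at an unadjusted p under 0.05. The same test called 3928 contigs with the rank of the stage in place of the day, 170 with no filter and 30 with the library set as a term. DESeq2's Wald test called 16135 contigs and limma on log2(TPM + 1) called 12455, of which 8196 were falling. At the adjusted limit the component calls rested on the libraries of days 2 and 4. Without day 2 there were 137 calls and without day 4 there were 527, against 4805 to 7109 without any other library. At an unadjusted p under 0.05 edgeR's test had 9433 components without day 2 and 9296 without day 4, against 12880 with all libraries. With the library set as a further term the test called 7947 components, and 6747 of the 7185 were among them. The sets were defined from these same counts and each holds early and late days, so this is no check for a batch.

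Few transcript units present at day 1 were no longer detected from day 4 on. By component, 78 of the 14275 with 100 or more counts at day 1 had fewer than 3 counts at day 4 and at day 5, or 0.546%. The median of these 78 went from 5.35 CPM at day 1 to 2.89 at day 2, 3.00 at day 2.5 and 0.522 at day 3, where 9 were already under 3 counts. The largest had 500 counts at day 1. Against a floor of 3 counts in the day 5 library they were 17.9-fold to 89.6-fold lower than at day 1. The mirror set was larger: 249 of 11018 components with 100 or more counts at day 5 had fewer than 3 at day 1 and day 2, or 2.26%. Their median reached 0.136 CPM at day 2.5, 2.14 at day 3, 5.36 at day 4 and 12.5 at day 5. At day 5 they were 62.0-fold to 2226-fold above the floor of the day 1 library.

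By contig, 622 of 18734 were no longer detected from day 4 on and 689 of 13549 appeared after day 2. In 553 of the 622, or 88.9%, the component still had 3 or more counts at day 4 or day 5, and in 316 it had 100 or more. Of the 689 that appeared, 439 lay in components already counted at day 1 or day 2.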

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

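Summing contigs by component, the scalings of component counts, every alternative of the component trend, the library set as a term, and peaks without day 2 or day 2.5 were chosen after seeing the data; the other alternatives were fixed before the data were examined. Under the alternatives 46 values stayed close to those reported, 39 moved and 1 reversed. For counts of changed features these labels compare totals alone, not directions. With the deposited TPM, 42.4% of contigs changed from day 1 to day 5 were higher, against 55.7%, yet this total is among the 46. From day 2.5 to day 3 the contig share went from 58.9% to 40.5%. The 39 include the log2 folds of the named contigs, some barely changed, such as 13.60 against 13.63 with DESeq2 size factors. The causes were not tested unless given. From day 1 to day 5, 16171 contigs changed 4-fold, against 3983 with a pseudocount of 5, 7690 at 8-fold and 9026 by component. In the order of the 5 consecutive intervals, a pseudocount of 5, which shrinks the folds of low contigs, left 553, 336, 1240, 534 and 396 contigs, with 38.7% higher in the second interval against 52.3%. Component sums gave 1538, 292, 2360, 1454 and 673, and with the deposited TPM the first 3 were 3120, 563 and 3975. The contig trend, 0 with edgeR and also 0 without any 1 library, gave 16135 with DESeq2's Wald test, 170 with no filter, 12455 with limma, 3928 with the rank of the stage, 30 with the library set as a term and 7185 by component. The component trend gave 12644 with DESeq2's Wald test and, leaving out 1 library at a time, 137 (day 2) to 7109 (day 3), with 527 without day 4. Contigs peaked at a stage, 19552, became 76290 with no filter, which adds contigs near 0, and 9670 by component; without day 2.5 those peaked at day 2 went from 1680 to 3058. Contigs lost after day 1, 622, became 1990 from 30 counts, 1347 when day 5 alone decided and 78 by component. The correlation of days 1 and 5, 0.455, reversed to -0.329 among the 1000 most abundant contigs and was 0.618 by component. The medians of the 15 gene lists could not be computed without gene names, and no paired analysis was possible because each stage had 1 library. Counts under 3 in a library could not show whether a transcript was absent.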

Other observations

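All of the tests in this part except that of reads taken up by other contigs of a component were chosen after the results they bear on had been seen, and the sets of 36, 90 and 573 below were picked from the 10 ways of setting 3 libraries against 3. A small group of components was counted almost only in the 3 middle stages. In 36 components the libraries of days 2, 2.5 and 3 were each more than 4-fold above those of days 1, 4 and 5. Their median was 0 counts at day 1, 31 at day 2, 54 at day 2.5, 21 at day 3, 2 at day 4 and 0 at day 5. Under the same rule 1705 components were higher in days 3, 4 and 5 than in days 1, 2 and 2.5, and 355 were higher in the earlier 3 days. The trend itself stood apart from other orderings of the days. Of 51 orderings of the days, 50 of them drawn at random and mirror images counted once, 1 gave as many components with a linear trend as the real order, namely the real order itself. The real order called 7185 components, and the highest of the other 50 called 66. Without day 2 the real order called 137, and without day 4 it called 527.

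In 573 contigs the libraries of days 1, 2.5 and 5 all lay 4-fold above or below those of days 2, 3 and 4, the most of any split of 3 libraries against 3 except the split of early from late days (3992). A change in the level of the whole gene is argued against, since components did so at 4.79% of the contig rate (18 of 31146). Random assignment of shared reads among near-identical contigs stays open. Among 3871 components with no such contig, 2.58% (95% interval 2.11 to 3.13) moved more than 0.5 of their reads to other contigs between days 1 and 2.5. Between days 1 and 2 the share was 4.37% (3.74 to 5.06). The shares of 6.51% (5.75 to 7.33) between days 2 and 3 and 7.72% (6.90 to 8.61) between days 2.5 and 3 have overlapping intervals. These shares come from the same components, so neither overlap nor separation of the intervals tests their difference. Days 4 and 5, which the split parts, had 3.20%, less than the 5.30% of days 3 and 4. Sequence variants of different parents assembled as separate contigs, or splice forms that differ between embryo batches, may also lie behind the pattern: in 60.4% of the 573 a contig of the component moved the opposite way, against 44.5% on average and 48.7% at most in 100 random draws, but any exchange of reads within a component whose sum holds steady gives such partners.

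A set of 90 components stood out by its counts over the libraries, and whether it came from a single added source stays open. Their counts summed to 422 CPM, here without TMM scaling, at day 2.5, 134 at day 4 and 253 at day 5, against 0.411 at day 1, 9.32 at day 2 and 6.55 at day 3. They were shorter (median of the longest contig 855 nt, against 1295 nt in the other tested components), and 82.2% had a single contig, against 56.9%. These comparisons were not matched for abundance, so they do not tell a source apart. RNA of another organism or cell source added in different amounts to some libraries would keep its counts in 1 ratio. Over days 2.5, 4 and 5 the chi-square per degree of freedom of the 90 against a common ratio was 4.86. The lowest of 1000 random sets of like abundance was 19.6. The lowest of 1000 sets chosen by the same rule on days 3, 4 and 5 was 7.66. Yet 4.86 lies above the 1 of counting error alone, so a strict common ratio was not met. Neither kind of set was picked on days 2.5, 4 and 5, so the lower value does not decide for an added source. Lower depth of the libraries of days 1, 2 and 3 is argued against by a ratio of totals of 0.887. A co-regulated group of lamprey genes stays open, since no sequence or name of these contigs was used here. That 79 of the 90 are among the components 4-fold higher at day 5 follows largely from how they were picked. It does not bear on their source.

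More contigs than components were lost after day 1. A shift of reads to other contigs within a component of steady level requires those contigs to gain what was lost. From day 1 to day 5 the other contigs gained at least 0.5 of the lost CPM in 16.1% (95% interval 13.3 to 19.2). Most of the 622 thus showed no shift of that size, and 53 of them had no other contig in their component. Like contigs that were not lost gave 29.8% on average and 33.8% at most in 100 draws. Those contigs were not chosen for a fall, so their higher share does not decide. For the 100 contigs that met the bound such a shift stays open. Where a whole component fell, its remaining reads could have gone to its other contigs without such a gain, which also stays open. In 316 of the 622 the component still had 100 or more counts at day 4 or day 5. Lower depth of the day 5 library is argued against by the TMM-scaled library totals. At the limit of 100 counts they leave at least 51.7 counts expected at day 5 for the contigs and 53.8 for the 78 components. The 78 components are candidates for a follow-up on DNA, which could tell degraded maternal RNA from genes lost with the eliminated part of the genome; neither was tested here.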
